A study of Homo sapiens with 24 samples.

How the data were processed

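The samples were 24 bulk RNA sequencing libraries from human tissue, 1 column each in 1 table of whole-number counts per gene symbol deposited by the authors. Tissue came from deceased organ donors, the molecule was total RNA, and libraries were prepared and sequenced at a core facility, per the labels' protocols. The series design text names tissue-resident memory T cells from donor-matched tissues and blood effector memory T cells. No blood sample was among the 24, so blood was not analysed here. The labels state no sorting gate or surface marker for any library. The aligner, the counting tool, the genome build, the annotation and the strandedness of the kit are not given in the sources used here, so no coordinates are printed. The counts are read as unnormalised, since they are whole numbers and their totals differ between libraries from 33789033 to 100585642. The deposited table says by its own name that genes were filtered, and the filter is not stated. The labels put all 24 libraries in 1 batch.

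Each library was placed in a group by the tissue and the lean or obese status in its labels. This gave 5 lean and 3 obese pancreas libraries, 4 lean and 1 obese jejunum libraries, and 4 lean and 4 obese libraries labelled spleen/PLN. PLN is the pancreas-draining lymph node, and the labels do not say whether a spleen/PLN library holds spleen, node or both. A further 1 lean and 1 obese library were labelled PLN alone. For 1 library the labels disagreed on the tissue, so it entered no comparison. The libraries came from 10 donors, and pairs of tissues were matched by the donor that their labels share. Deviations from the group mean correlated more between tissues of 1 donor (mean Pearson r = 0.184 over 14 pairs) than between tissues of different donors (mean −0.0474 over 54 pairs). Those correlations run across 6787 genes, which are not independent replicates. No 2 libraries were identical in every row.

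The row names were checked first. Of 12904 rows, 125 held no counts and 1511 shared their counts in all libraries with at least 1 other row. Rows named for retired or non-coding genes often repeated another row, such as 207 microRNA rows with 1 set of counts between them. Tests therefore used the 10983 rows with a current protein-coding symbol and counts of their own. Of the 1921 rows left out, 1741 had no current coding symbol, 125 no counts, 42 repeated the counts of another coding symbol, and 13 were sex-linked genes, which were left out to protect the donors. The rows used held 93.6 to 95.5% of each library's deposited counts.

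Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Rows were filtered with filterByExpr on the groups of each fit, libraries were scaled by TMM, and the quasi-likelihood F test was adjusted by Benjamini-Hochberg at a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Obese and lean libraries of a tissue were compared in a fit of that tissue alone. The lean tissues were compared in 1 fit of 13 libraries with the donor as a block. The obese tissue contrast, and its difference from the lean one, came from 1 fit of 16 pancreas and spleen/PLN libraries with the donor as a block. A donor block compares tissues within donors. Lean donors with both tissues numbered 4 for pancreas and jejunum, 4 for pancreas and spleen/PLN and 3 for jejunum and spleen/PLN. Obese donors with both pancreas and spleen/PLN numbered 3. The group means and their n count every library, paired or not. CPM values, the deposited counts scaled to a common library total, were computed with TMM factors over all 24 libraries, while each fold change used the factors of its own fit. Group values are the mean CPM ± SD.

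Before the data were examined, 40 gene lists were fixed. Lists with at least 5 tested members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated from the libraries. The list test by fry was run beside it. It asks whether the genes of a list move one way on balance, without comparing them with other genes. Adjusted p-values of lists are over all lists of a comparison. Of the 28 acinar, 18 ductal and 30 intestinal epithelial markers, 0 had a row to use. Rows to use existed for 4 of 19 islet, 2 of 18 fibroblast and stellate, 2 of 18 endothelial and 2 of 16 adipocyte markers. List scores are the mean log2(CPM + 1) of a list's members, compared by a 2-sided exact permutation test. The rule for named genes was also fixed in advance. It took the 12 largest rises and the 12 largest falls past the threshold with a mean of at least 16 CPM in the higher group. It added up to 4 members past the threshold per list and 9 residency genes whatever their p. Where fewer than 5 genes passed, it took the 10 with the lowest p. Genes that can tell of a donor's sex or genotype were never named.

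Alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, other scalings, filters and fold minimums, no donor block, the donor as a random effect, marker scores as covariates, 1 fit of all groups with at least 3 libraries, and leaving out each library in turn. Added after the data were seen were 2 other choices of rows and the macrophage score as a covariate in 5 further comparisons. Other splits of the libraries were refitted, all of them or 60 drawn with a fixed seed. In the obese tissue contrast only, splits that give the same term count once, a rule set after degenerate splits were seen.

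The gene tests of each comparison were run with edgeR on simulated counts with 200 changed genes, drawn from the means and totals of the real libraries. Each set was drawn 1 time, with the spread between libraries that edgeR estimated and no donor effect, a setting that can favour edgeR. In the simulated obese against lean pancreas comparison over 10391 genes, edgeR recovered 11.9% of genes changed 2-fold, 65.7% of those changed 4-fold and 81.8% of those changed 8-fold, and 2.75% of its calls were false. DESeq2 recovered 25.4, 74.6 and 92.4% there, with 23.4% of its calls false. In the simulated difference between obese and lean tissue contrasts over 10722 genes, edgeR recovered 1.49, 17.9 and 57.6%. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.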

Results

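Gene expression was measured by bulk RNA sequencing in 24 libraries of tissue from deceased organ donors. The series describes them as resident memory T cell profiles of donor-matched tissues. The groups were lean pancreas (n = 5), obese pancreas (n = 3), lean jejunum (n = 4), lean spleen/PLN (n = 4) and obese spleen/PLN (n = 4), where PLN is the lymph node that drains the pancreas. Single libraries stood for obese jejunum, lean PLN and obese PLN, and 1 library with conflicting tissue labels entered no comparison. Deposited counts per library ran from 33789033 to 100585642, and 10 genes held between 6.78 and 19.6% of the counts in the rows used. T cell identity genes, among them CD3E and CD8B, summed to 3780 ± 545 CPM (SD, n = 5) in lean pancreas, 5496 ± 710 (n = 3) in obese pancreas, 6015 ± 870 (n = 4) in lean jejunum, 5687 ± 797 (n = 4) in lean spleen/PLN and 7374 ± 1546 (n = 4) in obese spleen/PLN. All fold changes are on the log2 scale with their standard error, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p unless another tool is named.

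**Figure D1:**
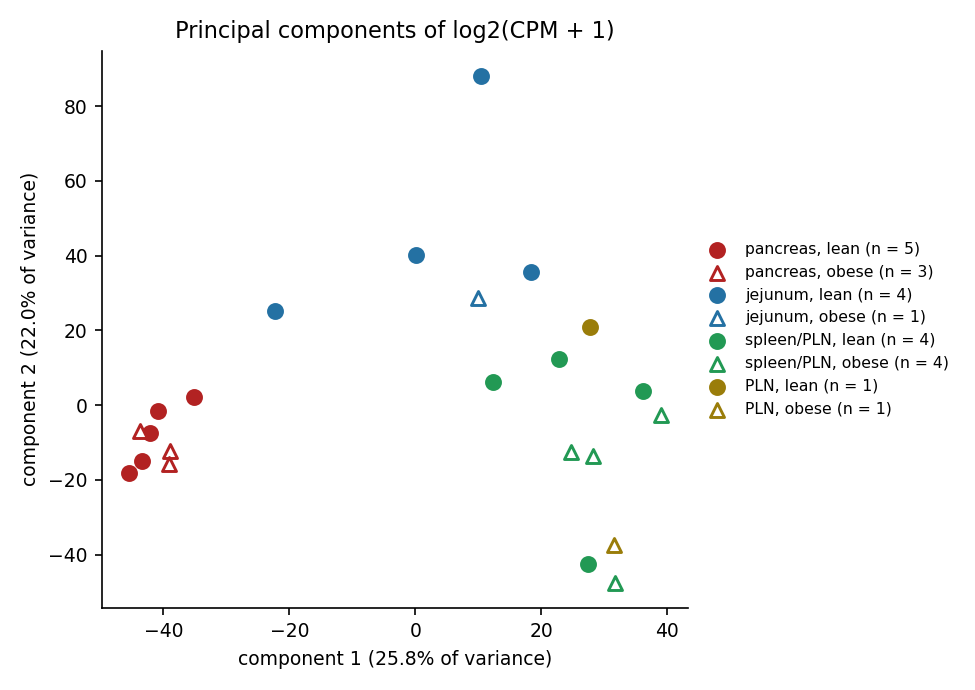
Principal components of log2(CPM + 1) over 6827 genes, 1 point per library, with component 1 (25.8% of the variance) on the x axis and component 2 (22.0%) on the y axis; colour gives the tissue and open triangles mark obese donors. The 8 pancreas libraries lie between −45.5 and −35.1 on component 1, and the 8 spleen/PLN libraries between 12.4 and 39.0.

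The tissue of origin separated the libraries. Pancreas libraries took the lowest values on the first component, from −45.5 to −35.1, jejunum lean libraries ran from −22.3 to 18.3, and spleen/PLN libraries from 12.4 to 39.0. Obese pancreas libraries (−43.7 to −39.0) fell within the range of the lean ones (−45.5 to −35.1). On the second component the 4 lean jejunum libraries ran from 25.1 to 88.0 and the single obese jejunum library was at 28.6, while the other groups stayed at 21.0 or lower.

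The comparison of obese with lean pancreas addressed the subject of the series title, the immune landscape of the pancreas in obesity. APOE, an apolipoprotein that macrophages and other cells make, was 14.5-fold higher in the obese libraries (91.4 ± 51.5 CPM, n = 3, against 6.26 ± 1.14, n = 5; log2 fold change 3.85 ± 0.34; adjusted p = 0.00176). HLA-DRA, the alpha chain of the antigen-presenting molecule HLA-DR, was higher as well (98.5 ± 48.3 against 15.6 ± 5.29 CPM; log2 fold change 2.65 ± 0.35; adjusted p = 0.0459). Both genes were higher in each of the 3 obese libraries than in any of the 5 lean ones. These were the 2 genes past the threshold of 10391 tested, and 883 had an unadjusted p under 0.05 where chance gives 520. Next by p, and not past the threshold, came MX1, an interferon-induced antiviral GTPase (237 ± 50.3 against 83.6 ± 15.6 CPM, adjusted p = 0.0541). It was followed by SOD2, a mitochondrial antioxidant enzyme induced by inflammatory signals (1084 ± 422 against 250 ± 66.6 CPM, adjusted p = 0.0551). The remaining genes of lowest p were FCER1G and FCGR2A, parts of Fc receptors of myeloid cells (log2 fold changes 3.35 ± 0.55 and 4.37 ± 0.74), and TIMP1, a metalloproteinase inhibitor (2.76 ± 0.49). Others were GPX1, a glutathione peroxidase (1.03 ± 0.19), MFGE8, a bridge for the uptake of dying cells (2.81 ± 0.51), and ZSWIM3 (2.72 ± 1.31 CPM in lean and 0.0250 ± 0.0228 in obese pancreas). FCGR2A has near-identical copies, so its counts are uncertain.

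Among the lists fixed in advance with at least 5 tested members, macrophage and monocyte markers had the largest median log2 fold change between obese and lean pancreas, 2.25 over 15 tested members (camera adjusted p = 6.35e-13). The call was lost with an estimated correlation (adjusted p = 0.45). Of these members, 0 passed over all genes by edgeR and 8 were higher adjusted over the list alone. Across all 10391 genes DESeq2 called 76, limma voom with quality weights 4. Summed over the list, these markers reached 191 ± 108 CPM in obese and 59.6 ± 7.05 CPM in lean pancreas. Complement subunit C1QA (22.3 ± 16.9 against 3.30 ± 1.48 CPM) and the monocyte receptor CD14 (17.1 ± 11.2 against 3.56 ± 2.09 CPM), members chosen after their values were seen, did not pass singly. Type I interferon response genes had a median of 0.79 over 27 members (camera adjusted p = 3.4e-08, and 0.45 with an estimated correlation), with 0 past over all genes and 11 higher and 2 lower adjusted over the list alone. T cell identity (median 0.36), oxidative phosphorylation (0.34) and cytotoxic effector genes (0.45) were also called higher at the preset correlation (camera adjusted p = 0.000249, 4.22e-05 and 0.00452). These calls too were lost with an estimated correlation (adjusted p = 0.45, 0.741 and 0.726). Immediate early and heat shock genes were called lower (−0.37, adjusted p = 0.0007, and 0.741 with an estimated correlation), with 0 past over all genes and 3 lower adjusted over the list alone. Without 1 library the immediate early median ran from −0.56 to −0.11 with an adjusted p of up to 0.125, and that of the cytotoxic list reached 0.0733. The other 4 of the 6 calls held in each of the 8 fits. With the macrophage score as a covariate 1 of the 6 held, oxidative phosphorylation, and by the list test fry 0 did. The macrophage list was there set against its own score, so its loss was built in and tells nothing.

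Residency genes did not pass between obese and lean pancreas. ITGAE, the CD103 integrin chain that binds epithelial cadherin, was at 269 ± 110 CPM in obese and 175 ± 33.4 in lean libraries (adjusted p = 0.59). CXCR6, a chemokine receptor of tissue T cells, was at 510 ± 247 against 276 ± 84.8 CPM (adjusted p = 0.494), and CD69, which holds T cells in tissue, at 751 ± 301 against 1347 ± 232 CPM (adjusted p = 0.471). The 21 residency genes expected higher in resident cells had a median of −0.37 (camera adjusted p = 0.596) and the 18 expected lower a median of 0.24 (0.349). Islet marker scores, which rest on 4 of the list's 19 genes, were 2.58 ± 0.246 in the obese and 1.10 ± 0.172 in the lean libraries. Macrophage scores were 2.70 ± 0.853 and 1.24 ± 0.238. For each, the 2-sided exact permutation p was 0.0179, the smallest that 56 splits can give, and the adjusted p 0.116 over 13 lists. CHGB, a secretory granule protein of endocrine cells, was at 33.9 ± 5.53 CPM in obese and 2.96 ± 2.57 in lean pancreas. APOE passed without any 1 of the 8 libraries (adjusted p from 0.000754 to 0.0162), while HLA-DRA passed in none of those 8 fits (from 0.0586 to 0.129). The count of 2 genes was 1 without lean replicates 2, 3, 4 or 5 or obese replicates 1 or 3, and 3 without lean replicate 1. Both calls ended with the macrophage score as a covariate (log2 fold changes 2.73 and 1.38, adjusted p = 0.277 and 0.358) and in 1 fit of all groups (adjusted p = 0.879 for both). The macrophage sums did not overlap between obese and lean pancreas (120 to 316 and 54.0 to 71.5 CPM). The covariate can therefore also take up part of a difference between the groups.

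**Figure D2:**
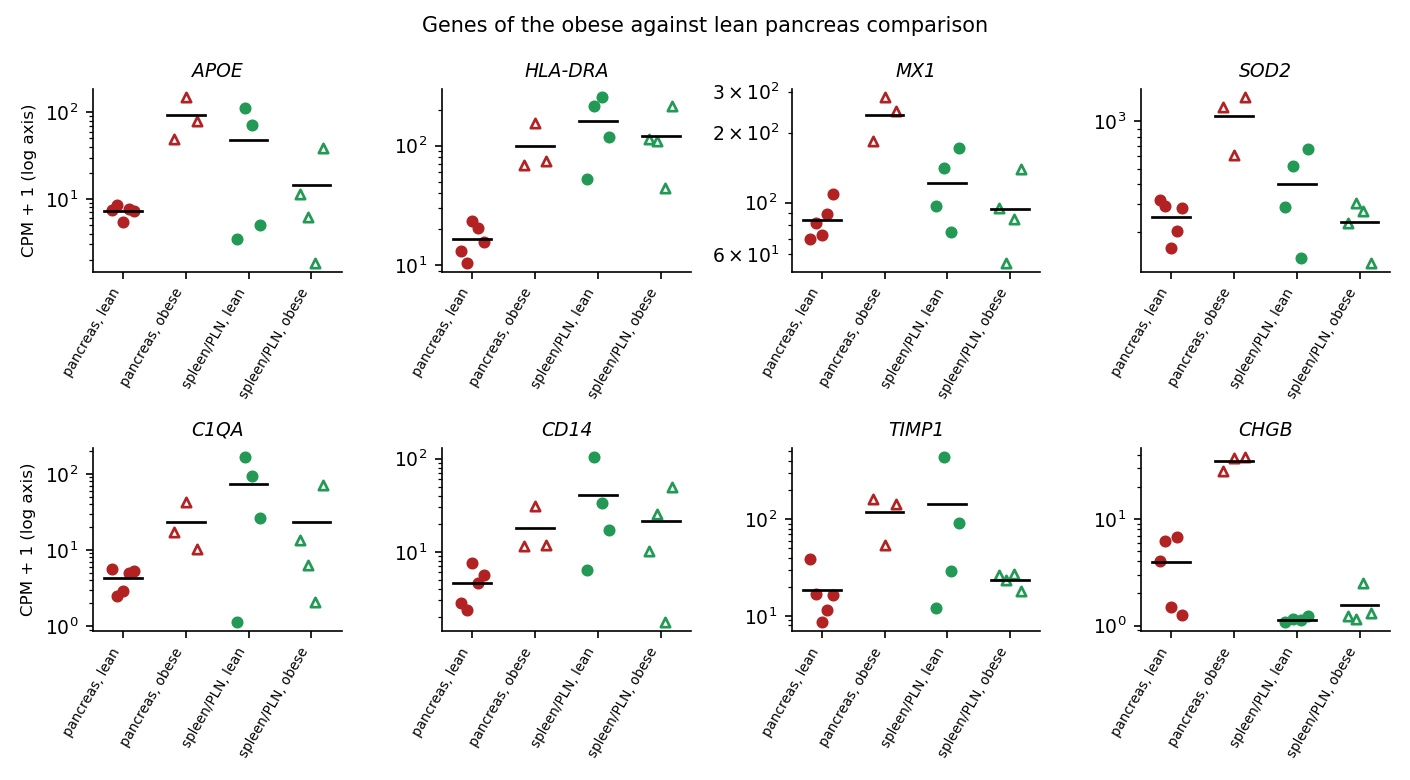
CPM + 1 on a log axis for 8 genes in lean (filled) and obese (open) libraries of pancreas and spleen/PLN, with black lines at group means. APOE lies between 47.9 and 148 CPM in the 3 obese pancreas libraries and between 4.42 and 7.54 in the 5 lean ones. Between obese and lean pancreas, APOE and HLA-DRA passed the test, and MX1, SOD2, C1QA, CD14, TIMP1 and CHGB did not.

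The comparison of obese with lean spleen/PLN asked the same of the lymphoid libraries. No gene passed by edgeR among 10309 tested, 297 had an unadjusted p under 0.05 where chance gives 515, limma voom with quality weights called 0 and DESeq2 5. The gene of lowest p was FGFBP2, a granule protein of cytotoxic lymphocytes (144 ± 99.1 CPM in obese, n = 4, and 21.4 ± 4.12 in lean libraries, n = 4; log2 fold change 2.73 ± 0.45, adjusted p = 0.708). Others were ITGAM, an integrin chain of myeloid and cytotoxic cells (29.7 ± 4.47 against 7.42 ± 3.22 CPM), and FCRL3, an Fc receptor-like protein (195 ± 87.5 against 57.9 ± 25.0 CPM). Lower in the obese libraries and not past the threshold were ADM, the vasodilator peptide adrenomedullin (6.25 ± 2.49 against 47.8 ± 41.8 CPM), IER3, an immediate early gene (12.5 ± 9.04 against 47.5 ± 14.1 CPM), and SREBF1, a regulator of lipid synthesis (52.9 ± 8.22 against 103 ± 8.98 CPM). The 5 genes of DESeq2 include FGFBP2, ITGAM, ADM and TREML2, and the other one is not named because it can tell of a genotype. These 4 were singled out after the values were seen.

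At the preset correlation, 3 lists were called higher in obese spleen/PLN by camera, namely T cell identity (median 0.34, adjusted p = 0.00266), genes expected lower in resident cells (0.27, 0.00909) and cytotoxic effector genes (0.27, 0.00319). Called lower were NF-kB and TNF response genes (median −0.77, adjusted p = 6.13e-05), hypoxia genes (−0.36, 0.00319), gamma delta and MAIT markers (−0.98, 0.00333), macrophage markers (−1.29, 0.00524), T cell cytokines (−0.55, 0.00909) and CD4 helper markers (−0.35, 0.0113). All 9 calls were lost with an estimated correlation, where the lowest adjusted p was 0.462. Leaving out each of the 8 libraries in turn kept 1 of the 9 throughout, T cell identity (adjusted p up to 0.0454). Its median then ran from 0.14 to 0.52, that of lower-residency genes from 0.07 to 0.35 and that of cytotoxic genes from 0.04 to 0.36. Among the lists called lower the medians ran from −1.10 to −0.58 for NF-kB genes, −0.63 to −0.16 for hypoxia genes and −1.49 to −0.20 for gamma delta and MAIT markers. For macrophage markers they ran from −2.45 to −0.41, for T cell cytokines from −0.85 to −0.17 and for CD4 helper markers from −0.84 to −0.31. By fry 0 of the 9 lists were called. Over all genes 0 members of these lists passed by edgeR, and adjusted over the list alone the counts were 1 of 19 lower-residency genes, 1 of 15 cytotoxic genes, 1 of 19 NF-kB genes and 1 of 16 hypoxia genes. Macrophage markers summed to 520 ± 314 CPM in obese and 785 ± 733 CPM in lean spleen/PLN.

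The lean pancreas was compared with lean spleen/PLN to ask how pancreas T cells differ from those of lymphoid tissue within donors. S1PR5, a receptor for the egress signal sphingosine 1-phosphate, was at 4.77 ± 2.96 CPM in pancreas (n = 5) and 295 ± 102 in spleen/PLN (n = 4; log2 fold change −6.19 ± 0.96, adjusted p = 0.00549). KLF2, the transcription factor that drives egress receptors, was at 48.4 ± 18.9 against 707 ± 490 CPM (−3.72 ± 0.48, 0.00258). ITGA1, the collagen-binding CD49a chain of resident T cells, was higher in pancreas at 130 ± 38.4 against 36.7 ± 32.0 CPM (1.95 ± 0.50, 0.0421). ITGAE, at 175 ± 33.4 against 78.8 ± 39.4 CPM, and CD69, at 1347 ± 232 against 2929 ± 1010 CPM, did not pass (adjusted p = 0.0680 and 0.0676).

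In all, 718 of 10415 genes passed in this contrast, 215 higher and 503 lower in pancreas. Of 19 genes expected lower in resident cells, 5 were lower and 0 higher over all genes, and 13 were lower adjusted over the list alone (median −3.34, camera adjusted p = 1.2e-11, and 0.0135 with an estimated correlation). Of 15 cytotoxic effector genes, 6 were lower and 0 higher (12 adjusted over the list alone), with KLRG1, a receptor of effector cells (3.61 ± 1.01 against 176 ± 59.8 CPM), granzyme gene GZMK (14.5 ± 7.13 against 571 ± 222 CPM) and granule gene NKG7 (33.7 ± 17.6 against 479 ± 73.9 CPM) among them. NK receptors on T cells had 7 of 15 members lower, among them KLRF1, NCR3 and CD160 (log2 fold changes −6.99 ± 1.14, −6.41 ± 1.10 and −5.01 ± 0.69). Inhibitory receptors had 7 of 13 lower, including SIRPG and HAVCR2, the latter encoding TIM-3 (−4.78 ± 0.70 and −3.27 ± 0.84). T cell cytokines had 9 of 18 lower, including LTB, lymphotoxin beta (7.37 ± 6.26 against 172 ± 107 CPM, adjusted p = 8.34e-05), and activation genes 9 of 17. Interferon gamma response genes had 8 of 18 lower, including GBP5 (−2.08 ± 0.41). For the NK receptor, inhibitory receptor, cytokine, activation and interferon gamma lists the adjusted p with an estimated correlation was 0.0135, 0.0361, 0.0463, 0.0451 and 0.0355. Adjusted over the list alone, 10, 8, 10, 12 and 15 of their members were lower and 1, 0, 1, 0 and 0 higher. The lists of T cell identity (5 of 13 lower), naive and central memory (4 of 16), and gamma delta and MAIT genes (5 of 7) also kept their calls, with an adjusted p of 0.0361, 0.0361 and 0.0135. Adjusted over the list alone, 7, 9 and 6 were lower and 0, 1 and 0 higher.

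Genes of sugar metabolism and hypoxia were among those higher in lean pancreas than in lean spleen/PLN. PGK1, a glycolytic kinase, was at 3506 ± 1143 against 947 ± 430 CPM (log2 fold change 2.10 ± 0.42). PDK1, a pyruvate dehydrogenase kinase, was at 86.4 ± 38.1 against 20.4 ± 6.23 CPM, and EGLN1, an oxygen-sensing hydroxylase, at 220 ± 51.5 against 76.6 ± 8.01 CPM. Of 16 hypoxia genes 5 were higher and 0 lower (7 higher and 1 lower adjusted over the list alone; median 0.69, camera adjusted p = 0.000377). Of 19 glycolysis genes 2 were higher and 0 lower (6 adjusted over the list alone; median 0.85, 9.56e-05). Both calls were lost with an estimated correlation, with an adjusted p of 0.257 and 0.197. The largest rises included CAMK1D, a calmodulin-dependent kinase (3.22 ± 0.63), GAB2, a signalling adaptor (3.03 ± 0.58), and RXRA, the retinoid X receptor (2.93 ± 0.73). Others were ARHGEF7, an exchange factor of small GTPases (2.85 ± 0.48), ABLIM1, an actin-binding protein (2.65 ± 0.38), and GALNT2, an enzyme of O-glycosylation (2.45 ± 0.25). Of 24 immediate early genes 4 were lower (8 adjusted over the list alone; JUN −1.78 ± 0.47; camera adjusted p = 2.66e-06, and 0.233 with an estimated correlation).

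Markers of other cell types moved with this contrast. Macrophage markers summed to 785 ± 733 CPM in lean spleen/PLN and 59.6 ± 7.05 CPM in lean pancreas, and 8 of 16 were lower in pancreas (10 adjusted over the list alone; estimated-correlation adjusted p = 0.0361), with S100A8 at 0.0913 ± 0.132 against 118 ± 155 CPM. B cell markers summed to 163 ± 166 CPM in lean spleen/PLN and 14.2 ± 3.64 CPM in lean pancreas, and erythroid and platelet markers to 361 ± 317 and 23.8 ± 8.31 CPM. NK cell markers summed to 971 ± 153 and 852 ± 580 CPM, with list scores of 4.37 ± 0.134 and 2.88 ± 0.472. CD4 helper marker scores were 4.30 ± 0.511 and 2.72 ± 0.515. The NK cell list shares members such as KLRF1 and GNLY with the NK receptor and cytotoxic lists. HBA2, a haemoglobin gene with a near-identical copy and so of uncertain count, was among the largest falls (−8.22 ± 1.27), as was IGLL5, which shares sequence with immunoglobulin lambda genes (−8.54 ± 1.37). With the macrophage score as a covariate, an alternative added after the data were seen, 1 gene passed, KLRG1 (−5.44), and ITGA1 and IGLL5 turned in direction (−0.51 and 0.94). The macrophage sums did not overlap between these tissues (54.0 to 71.5 CPM in pancreas, 160 to 1821 in spleen/PLN). The covariate can therefore also take up part of the tissue difference, and its result does not give the cause. The count of 718 fell to 264, 277, 455, 448 and 428 without pancreas replicates 1, 2, 3, 4 and 5. It fell to 239, 260 and 292 without spleen/PLN replicates 1, 2 and 3, and to 441 without jejunum replicate 2. Scaling by library totals alone moved the median of all genes from 0.02 to 0.31 and gave 523 higher and 360 lower genes. DESeq2 gave 1732 genes, limma voom with quality weights 1516 and a random donor effect 1270.

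**Figure D3:**
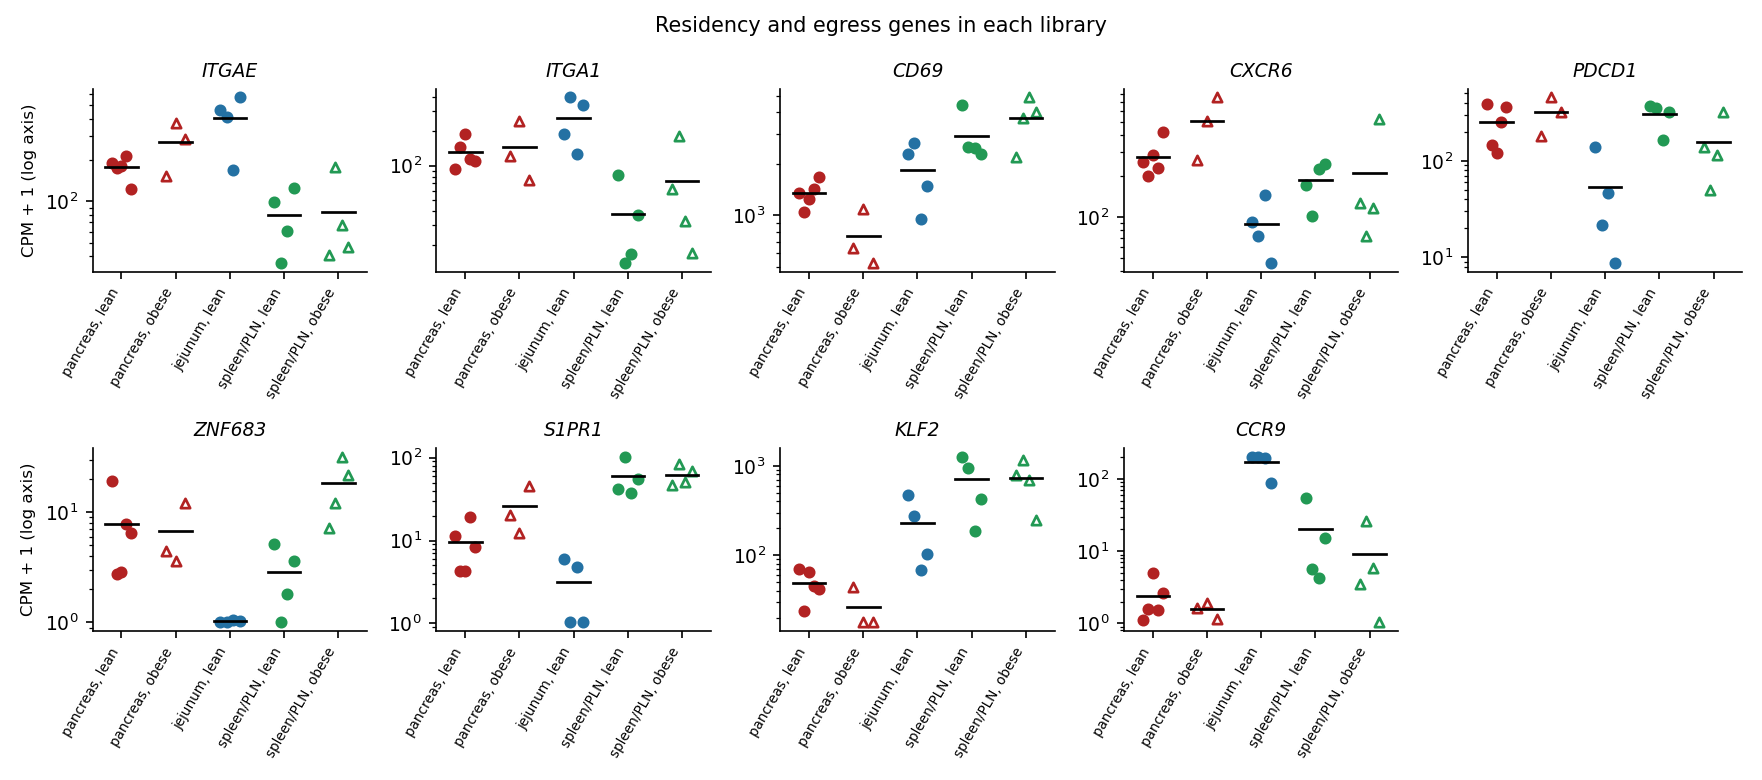
CPM + 1 on a log axis of 9 residency, egress and homing genes in each library of 5 groups, with black lines at group means; filled circles are lean and open triangles obese donors. KLF2 lies between 188 and 1268 CPM in the 8 spleen/PLN libraries and between 16.7 and 69.1 in the 8 pancreas libraries; not every difference shown passed the test.

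Lean pancreas against lean jejunum compared 2 tissues that both hold resident T cells. CCR9, the gut-homing chemokine receptor, was at 1.39 ± 1.60 CPM in pancreas (n = 5) and 171 ± 56.3 in jejunum (n = 4; adjusted p = 0.00611). CD160, a receptor of intestinal and cytotoxic lymphocytes, was at 3.19 ± 1.92 against 191 ± 110 CPM (log2 fold change −5.70 ± 0.74, 0.00611). Higher in pancreas were PDCD1, encoding the checkpoint receptor PD-1, at 253 ± 121 against 52.7 ± 58.4 CPM (2.58 ± 0.60, 0.0237), and CXCR6, at 276 ± 84.8 against 88.0 ± 42.0 CPM (1.83 ± 0.36, 0.0154). ITGAE (175 ± 33.4 against 402 ± 169 CPM, adjusted p = 0.146) and CD69 (1347 ± 232 against 1836 ± 760 CPM, 0.651) did not pass.

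Of 10415 genes 1195 passed, 525 higher and 670 lower in pancreas. Among the largest rises were NELL2, a gene of less differentiated T cells (138 ± 68.5 against 5.14 ± 6.77 CPM), RASA3, a regulator of small GTPases (5.45 ± 0.96), and HK2, hexokinase 2 of glycolysis (8.54 ± 2.23). Others were MYO6, a myosin motor (3.85 ± 0.82), PIK3CB, a lipid kinase (3.43 ± 0.61), and FGFR1, a growth factor receptor (3.13 ± 0.85). Among the largest falls were TMIGD2, a costimulatory receptor (−4.31 ± 0.95), DTX1, a regulator in the Notch pathway (−4.25 ± 0.59), SIRPG, a CD47-binding receptor (−4.17 ± 0.76), and CH25H, which makes an oxysterol (−4.71 ± 1.25). Residency genes expected higher were mixed, with 4 higher, 1 lower and 16 not past (4 and 5 adjusted over the list alone).

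At the preset correlation camera called 8 lists between lean pancreas and jejunum, and none held with an estimated correlation, where the lowest adjusted p was 0.443. Oxidative phosphorylation genes had 8 of 25 members lower in pancreas and 0 higher (11 lower adjusted over the list alone), among them NDUFS5 and COX7C (−1.83 ± 0.23 and −1.36 ± 0.27). The list's median was −0.63 (camera adjusted p = 6.8e-06, and 0.741 with an estimated correlation) and −0.09 with scaling by library totals. T cell identity genes had 6 of 13 lower, adjusted over the list alone too, with CD3E at 176 ± 34.7 against 716 ± 309 CPM. Glycolysis genes had 4 of 19 higher, including PFKP (1.55 ± 0.27), and 1 lower (5 and 1 adjusted over the list alone). Hypoxia genes had 3 of 16 higher (5 adjusted over the list alone), including BNIP3L (1.49 ± 0.41). Immediate early and heat shock genes had 3 of 24 lower (3 adjusted over the list alone), with HSP90AA1, a chaperone, at 861 ± 676 against 16301 ± 21452 CPM. The camera adjusted p of the T cell identity, glycolysis, hypoxia and immediate early lists was 0.00772, 0.0158, 0.0414 and 0.00772. NK receptors (2 of 15 lower, 0.0103), inhibitory receptors (1 of 13 higher and 4 lower, 0.0414) and plasma cell markers (2 of 5 lower, 0.0361) were called as well. Adjusted over the list alone, 3, 8 and 3 of their members were lower and 0, 3 and 0 higher. Macrophage markers summed to 94.2 ± 12.4 CPM in jejunum and 59.6 ± 7.05 CPM in pancreas, and B cell markers to 33.6 ± 15.6 and 14.2 ± 3.64 CPM. The member CTSS alone held 68.8 ± 13.7 and 39.6 ± 7.25 CPM of the macrophage sums. Other macrophage members went both ways, with lower means in jejunum for C1QA, C1QB and CD14 and higher means for FCGR2A and S100A8.

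The count of 1195 genes between lean pancreas and jejunum, with CCR9 among them, fell to 215, 786, 222 and 661 without pancreas replicates 1, 2, 3 and 5. It fell to 329, 215 and 636 without jejunum replicates 1, 2 and 4, and to 762 without spleen/PLN replicate 2. Scaling by library totals alone moved the median of all genes from 0.11 to 0.60 and turned the split to 1382 higher and 292 lower. DESeq2 gave 2513 genes and a random donor effect 1875.

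Lean jejunum against lean spleen/PLN asked the same of the gut within donors. ITGAE, at 402 ± 169 CPM in jejunum (n = 4) and 78.8 ± 39.4 in spleen/PLN (n = 4), was higher in jejunum (log2 fold change 2.24 ± 0.42, adjusted p = 0.0341), as were ITGA1 (263 ± 128 against 36.7 ± 32.0 CPM; 2.70 ± 0.52, 0.0357) and NT5E, the ectoenzyme CD73 (2.05 ± 0.40, 0.0357). S1PR5 (1.34 ± 1.48 against 295 ± 102 CPM; −8.48 ± 1.07, 0.00641) was lower. PDCD1 (52.7 ± 58.4 against 301 ± 93.3 CPM, adjusted p = 0.0754) and KLF2 (229 ± 185 against 707 ± 490 CPM, 0.0924) did not pass.

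In this contrast 148 of 10415 genes passed, 34 higher and 114 lower in jejunum. Other rises were IL2, a T cell growth factor (59.6 ± 76.5 against 11.1 ± 18.1 CPM), SPRY1, a brake on receptor signalling (2.24 ± 0.42), DTX1 (3.02 ± 0.59), GAB2 (3.22 ± 0.62) and PARD6G, a polarity protein (3.49 ± 0.70). Of 19 genes expected lower in resident cells, 5 were lower (12 adjusted over the list alone; median −3.92, camera adjusted p = 4.28e-13, and 0.0403 with an estimated correlation). Cytotoxic genes had 6 of 15 lower (9 lower and 1 higher adjusted over the list alone), including GZMK, KLRG1 and FGFBP2 (−4.68 ± 0.55, −4.39 ± 0.31 and −8.77 ± 1.43), with adjusted p = 0.0736 with an estimated correlation. Interferon gamma response genes had 3 of 18 lower (10 adjusted over the list alone; 0.0698 estimated), including GBP5 and NLRC5 (−3.02 ± 0.48 and −2.54 ± 0.33). EOMES, a transcription factor of effector cells, and KLRF1 were lower (−4.70 ± 0.91 and −8.68 ± 1.26). Oxidative phosphorylation genes had a median of 0.64, and 0.40 with library totals, with 1 of 25 higher (5 adjusted over the list alone; camera adjusted p = 6.84e-07, and 0.229 estimated).

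Macrophage markers moved with this contrast too, at 94.2 ± 12.4 CPM summed in jejunum and 785 ± 733 CPM in spleen/PLN, with VCAN, a matrix proteoglycan of monocytes, and IL1B, an inflammatory cytokine, among the largest falls (−6.92 ± 1.42 and −9.11 ± 1.42). B cell markers summed to 33.6 ± 15.6 CPM in jejunum and 163 ± 166 CPM in spleen/PLN (median −3.43, estimated-correlation adjusted p = 0.221). Erythroid and platelet markers summed to 28.9 ± 24.4 and 361 ± 317 CPM (−4.07, 0.155). NK cell markers, which include KLRF1, summed to 676 ± 232 CPM in jejunum and 971 ± 153 CPM in spleen/PLN. With the macrophage score as a covariate, added after the data were seen, edgeR called 0 genes and 1261 had an unadjusted p under 0.05. Here too the macrophage sums did not overlap (79.3 to 109 CPM in jejunum, 160 to 1821 in spleen/PLN). The covariate can therefore also take up part of the tissue difference. Without the covariate DESeq2 called 1250 and limma voom with quality weights 171. The count of 148 fell to 52, 73, 89 and 51 without jejunum replicates 1, 2, 3 and 4. It fell to 40, 84, 32 and 78 without spleen/PLN replicates 1, 2, 3 and 4, and to 76 without pancreas replicate 3. Scaling by library totals alone moved the median of all genes from −0.08 to −0.29 and gave 21 higher and 146 lower genes. No donor block gave 265 and a random donor effect 392.

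The same contrast of pancreas with spleen/PLN in obese donors had 684 of 10722 genes past the threshold, 193 higher and 491 lower in pancreas. S1PR5 was at 2.29 ± 0.904 CPM in pancreas (n = 3) and 258 ± 57.3 in spleen/PLN (n = 4; log2 fold change −6.81 ± 0.69, adjusted p = 0.00168). The donor of obese spleen/PLN replicate 3 gave no pancreas library. The means include that library, while the fold changes of this contrast rest on 3 donor pairs. ITGAE was higher in pancreas at 269 ± 110 against 81.8 ± 63.8 CPM (1.82 ± 0.46, 0.0471), and CD69 lower at 751 ± 301 against 3707 ± 1125 CPM (−2.22 ± 0.40, 0.0153). CSF3, the granulocyte growth factor, was among the largest rises (130 ± 57.7 against 0.0571 ± 0.0506 CPM; 10.59 ± 0.94). Others were the neutrophil chemokine CXCL5 (28.8 ± 23.7 against 0.0265 ± 0.0236 CPM) and INHBA, an activin subunit (24.1 ± 13.4 against 2.04 ± 3.95 CPM). CHGB was higher as well (33.9 ± 5.53 against 0.552 ± 0.639 CPM; 7.13 ± 1.14). ZDHHC11 and ZDHHC11B, near-identical copies whose counts are uncertain, were also in this set.

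Genes expected lower in resident cells had 10 of 19 members lower in obese pancreas than in obese spleen/PLN (12 adjusted over the list alone; median −3.66, camera adjusted p = 3.86e-13, and 0.0294 with an estimated correlation). Among them were CX3CR1, a chemokine receptor of circulating effectors, and LEF1, a factor of naive T cells (−9.32 ± 1.39 and −7.52 ± 1.55). NK receptors had 5 of 15 lower (6 adjusted over the list alone; 0.0294 estimated), including FCGR3A, whose near-identical copy leaves its counts uncertain. Cytotoxic genes had 7 of 15 lower (9 adjusted over the list alone), with GZMA and GZMK at −5.51 ± 0.58 and −6.18 ± 0.58. That call was lost with an estimated correlation (adjusted p = 0.171). Hypoxia genes had 5 of 16 higher (8 adjusted over the list alone; median 1.19, camera adjusted p = 3.61e-07, and 0.182 estimated), including ADM and VEGFA, the angiogenic factor (3.32 ± 0.40 and 2.70 ± 0.69). Immediate early genes had 8 of 24 lower and 0 higher (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000152, and 0.382 estimated). B cell markers had 4 of 16 lower (7 adjusted over the list alone; 0.171 estimated), with CD79A, part of the B cell receptor, at 0.0900 ± 0.128 against 15.3 ± 13.5 CPM. Macrophage markers had a median of −0.59, and −0.30 with library totals, 3 of 16 lower (4 adjusted over the list alone; 0.522 estimated) and sums of 191 ± 108 against 520 ± 314 CPM. Erythroid and platelet markers had a median of −4.09, 1 of 8 lower (3 adjusted over the list alone; 0.171 estimated) and sums of 52.8 ± 63.2 against 424 ± 369 CPM. NK cell markers, which share members with the NK receptor and cytotoxic lists, summed to 869 ± 548 CPM in pancreas against 1117 ± 221 in spleen/PLN. Their list scores were 2.98 ± 0.312 and 4.29 ± 0.189, and those of CD4 helper markers 2.73 ± 0.373 and 3.71 ± 0.323.

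The count of 684 genes in obese donors, with CSF3 and S1PR5 among them, fell to 171, 158 and 100 without obese pancreas replicates 1, 2 and 3, and to 164, 147 and 87 without obese spleen/PLN replicates 1, 2 and 4. It was 166 with the macrophage score as a covariate, added after the data were seen. It was 1905 by DESeq2, 1836 by limma voom with quality weights, 1087 without the donor block and 1592 with a random donor effect. Library totals moved the median of all genes from −0.04 to 0.21, with 332 higher and 313 lower.

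The last comparison asked whether the contrast of pancreas with spleen/PLN differed between obese and lean donors. No gene passed by edgeR among 10722 tested, 516 had an unadjusted p under 0.05 where chance gives 536, limma voom with quality weights called 0 and DESeq2 62. Genes of lowest p were ADM (difference of log2 fold changes 2.97 ± 0.49), the lysosomal reductase gene IFI30 (4.04 ± 0.70) and CXCL5 (7.82 ± 1.37). Others were TNFRSF4, encoding OX40 (4.94 ± 0.95), TYMP, thymidine phosphorylase (2.87 ± 0.61), and GPX1 (1.87 ± 0.39), all with an adjusted p of 0.954. Lists called higher in the obese contrast were macrophage markers (median difference 2.89, camera adjusted p = 4.76e-09) and NF-kB and TNF response genes (0.84, 1.11e-05). Also called were type I interferon genes (0.76, 1.31e-05), gamma delta and MAIT markers (1.74, 1.99e-05), oxidative phosphorylation (0.48, 0.000104) and hypoxia genes (0.42, 0.0264). Of the 6 calls, 0 held with an estimated correlation, where the lowest adjusted p was 0.431, and 0 members of these lists passed over all genes by edgeR. Adjusted over the list alone, 2 macrophage, 2 NF-kB, 4 interferon, 3 gamma delta and MAIT, 0 oxidative phosphorylation and 1 hypoxia genes were higher. Residency genes did not differ past the threshold, with ITGAE at 0.59 ± 0.60 and CD69 at −1.11 ± 0.51 (adjusted p = 0.984 and 0.954).

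**Figure D4:**
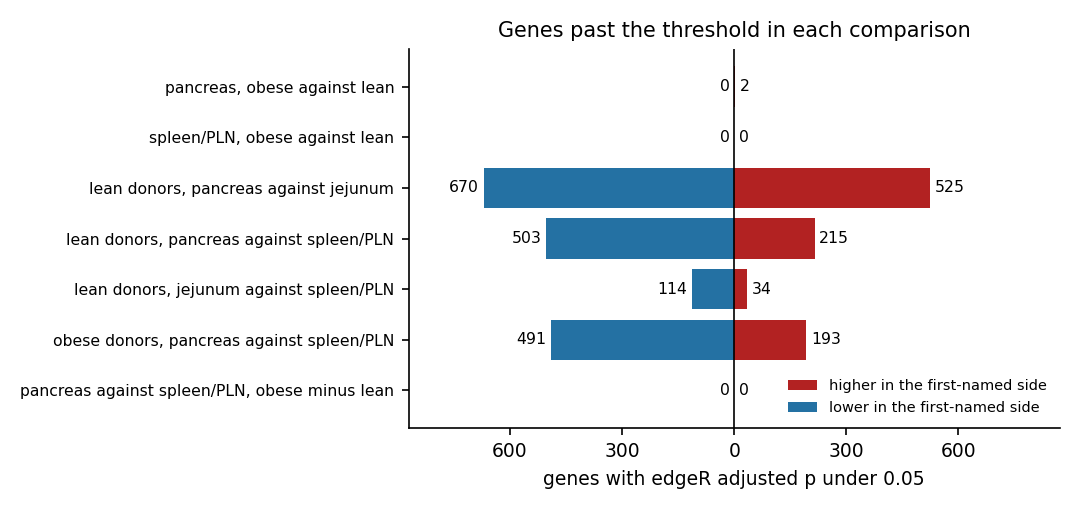
Genes with an edgeR adjusted p under 0.05 in each of 7 comparisons, higher in the first-named side to the right and lower to the left of 0. The obese against lean comparisons hold 2 genes in pancreas and 0 in spleen/PLN, and the tissue comparisons between 148 and 1195.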

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

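The tests chosen only after the result was seen were the share of macrophage members that are higher, both tests of the row names and the other splits of the libraries. In addition, the rules that read the interferon covariate test, the share of macrophage members and the splits for a count of 0 were changed after their values were seen.

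Macrophage and monocyte genes had a median log2 fold change of 2.25 between obese and lean pancreas, and 100% of the 15 tested members were higher in the obese libraries. That share restates the rise for which the list was picked out, so it does not favour RNA from macrophages or monocytes over another cause. Of the list's 16 genes, 8 reached a mean of 1 CPM in lean pancreas and 1 is in another list, and the most abundant members in obese pancreas were CTSS (59.9 ± 15.0 CPM) and C1QB (24.5 ± 18.8 CPM). With all 8 libraries thinned to the smallest total the median was 2.49 over 14 tested members. Thinning with rescaling leaves the expected fold change nearly unchanged, so this value does not decide on a difference in depth. Counts in the rows used ran from 48286704 to 61224143 in obese pancreas libraries, within the lean range of 31790732 to 80600885. Against 1 obese library carrying the difference stands a lowest median of 1.56 without 1 of them. The labels state no sort that would remove such cells, and the call was lost with an estimated correlation (camera adjusted p = 0.45). RNA from such cells and a biological difference between obese and lean donors were not tested apart, and both stay open.

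Type I interferon genes had a median of 0.79 between obese and lean pancreas and 0.51 as the lowest median without 1 obese library, which argues against 1 library carrying it. With the macrophage score as a covariate the median was 0.0338, with a standard error of 0.204 over members. That is the outcome written in advance for RNA from macrophages as the cause, but the score itself separates the groups (correlation with obese status 0.838 over 8 libraries), so the covariate can also take up part of a difference between the groups. The reading was therefore changed, after the value was seen, from support to undecided: RNA from macrophages and a difference between obese and lean donors cannot be told apart here. MX1 was at 237 ± 50.3 CPM in obese and 83.6 ± 15.6 CPM in lean pancreas.

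Rows named for retired or non-coding genes repeated the counts of other rows, and 517 of 903 such rows (57.3%) equalled the coding gene that sorts just before them, against 17 of 7461 coding rows (0.228%). A lookup of names in a sorted table that takes the nearest preceding name is a candidate explanation for these rows. Reads shared between paralogs would give many sets of counts among the 207 microRNA rows, which held 1. No biological explanation was tested, and such rows were left out of all tests but 2 alternatives.

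Other splits of the same libraries were refitted for each comparison. For obese against lean pancreas, 3 of 56 splits gave at least the real 2 genes and the highest other gave 6, so chance is not excluded. For spleen/PLN and for the difference between the tissue contrasts the real count was 0, which each of the 35 splits reaches whatever the data, so the splits decide nothing there (highest other 1). In the lean contrasts only the real split, among those run, reached the count. For pancreas against jejunum it gave 1195 genes, and the highest other of 60 splits, drawn from 126, gave 2. For pancreas against spleen/PLN it gave 718, and the highest other of 60 gave 92. For jejunum against spleen/PLN it gave 148, and the highest other of 35 gave 0. Most of these splits leave both tissues of some donor on the same side, where a fit with a donor block has less to compare. The splits that part as many donor pairs as the real one were 16, 16 and 8, with highest others of 0, 4 and 0. These are too few for a share under 0.05, so the splits do not exclude chance there. The obese contrast has 13 splits in all, also too few (684 genes, highest other 0).

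Single libraries stood far from the rest of their group on 11 of 188 measures, where chance gives 9.4, each given as the gap to the nearest library over the group's range. The gap was 0.965 for the total of jejunum lean replicate 4 and 0.840 for the second component of spleen/PLN lean replicate 3. For the score of genes expected higher in residency it was 0.958 in jejunum lean replicate 1, 0.882 in spleen/PLN lean replicate 1 and 0.844 in spleen/PLN obese replicate 3. It was 0.889 for genes expected lower and 0.911 for glycolysis in spleen/PLN lean replicate 3, 0.733 for interferon gamma response in pancreas lean replicate 5 and 0.902 for proliferation in jejunum lean replicate 1. For CD69 it was 0.905 in spleen/PLN lean replicate 1, and for CXCR6 0.882 in spleen/PLN obese replicate 4.

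The contrast of pancreas with spleen/PLN differed between obese and lean donors for 6 lists by camera at the preset correlation. The median differences were 0.84 for NF-kB, 0.76 for type I interferon, 0.48 for oxidative phosphorylation, 0.42 for hypoxia, 1.74 for gamma delta and MAIT and 2.89 for macrophage genes. None held with an estimated correlation, where the lowest adjusted p was 0.431.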

How the results depend on the processing

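The alternatives added after the data were seen were both other choices of rows and the macrophage score as a covariate in every comparison except obese against lean pancreas, where it was planned, and pancreas against jejunum, where it was not run. The planned acinar covariate was not run, since 0 of the 28 markers had a row. The count of 2 genes between obese and lean pancreas became 76 by DESeq2, 4 by limma voom with quality weights, 4 with library totals, 4 with a stricter filter, 0 in 1 fit of all groups, 1 with the macrophage covariate and 1 with 1 row per distinct set of counts. The 1 gene with the covariate was COL6A2, chosen after its value was seen. DESeq2 gave 5 genes for spleen/PLN, 2513 for pancreas against jejunum, 1732 for pancreas against spleen/PLN, 1250 for jejunum against spleen/PLN, 1905 for the obese contrast and 62 for the difference between contrasts. In simulated counts of 2 comparisons, 23.4 and 32.6% of its calls were false. Those counts followed edgeR's own estimate of the spread and had no donor effect. They therefore do not give the false share of DESeq2's calls in the real data. Limma voom gave 1516 for pancreas against spleen/PLN and 1836 for the obese contrast. A random donor effect gave 1875, 1270, 392 and 1592 in the lean pancreas against jejunum, pancreas against spleen/PLN, jejunum against spleen/PLN and obese contrasts, and no donor block 265 and 1087 in the last 2. The macrophage covariate gave 1, 0 and 166 in the pancreas against spleen/PLN, jejunum against spleen/PLN and obese contrasts. In both lean contrasts the macrophage sums of the tissues did not overlap, so the covariate can also take up part of the tissue difference. With the covariate the median of the macrophage list turned to 0.35 in obese against lean spleen/PLN. The score is made of the same genes, so that turn was built in and tells nothing of the list. In lean pancreas against spleen/PLN it turned IGLL5 to 0.94, LILRB2 to 1.18, ITGA1 to −0.51, the oxidative phosphorylation list to 0.54 and the plasma cell list to −0.00240, and in jejunum against spleen/PLN the NF-kB list to 0.10. LILRB2 and IGLL5 share sequence with related genes, so their counts are uncertain. Leaving out 1 library gave 1 to 3 genes for obese against lean pancreas, 215 to 1249 for pancreas against jejunum, 239 to 873 for pancreas against spleen/PLN, 32 to 123 for jejunum against spleen/PLN and 87 to 701 for the obese contrast. For the changes above the cause was not tested.

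Of the named genes past the threshold, every leave-out kept 23 of 98 in pancreas against jejunum, 32 of 92 in pancreas against spleen/PLN, 11 of 48 in jejunum against spleen/PLN and 21 of 90 in the obese contrast. Limma voom with quality weights kept 93, 92, 42 and 90, and library totals 81, 79, 44 and 82. With an estimated correlation 12 of 23 list calls held in pancreas against spleen/PLN, 1 of 18 in jejunum against spleen/PLN, 2 of 22 in the obese contrast and 0 in the others. Every leave-out kept 22 of 23, 13 of 18 and 15 of 22 of these, 3 of 8 in pancreas against jejunum, and 4 of 6, 1 of 9 and 4 of 6 in obese against lean pancreas, obese against lean spleen/PLN and the difference between contrasts. In that order of 7 comparisons fry kept 20, 16, 17, 4, 0, 0 and 0 of the list calls. The macrophage covariate kept 15, 5, 20, 1, 8 and 3, the same without pancreas against jejunum. Where the macrophage list was among the calls, it was set against its own score, so its own outcome there tells nothing. In simulated counts edgeR recovered 11.9% of genes changed 2-fold between obese and lean pancreas, so smaller differences would mostly be missed at this size and depth.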

Other observations

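No test in this part was chosen after its result was seen, except where stated. Of the 718 genes that differed between pancreas and spleen/PLN in lean donors, 697 had the same sign in obese donors (97.1%, against 74.5% of all genes). Of those higher in pancreas, 66 passed in both, where 3.96 are expected of independent lists, and of those lower 281, where 23.5 are expected. This is in line with the same tissue difference in the obese donors. The libraries share a batch and part of the fit, so these counts are not independent.

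Further tissue marker scores, each resting on 2 genes of its list, did not pass between obese and lean pancreas libraries. Fibroblast and stellate marker scores were 4.92 ± 0.900 in obese and 3.74 ± 0.541 in lean pancreas (2-sided exact permutation p = 0.0536, adjusted p = 0.232 over 13 lists). In spleen/PLN they were 5.36 ± 0.618 in obese and 5.01 ± 0.378 in lean libraries, so this score is not particular to the pancreas. Endothelial scores were 4.16 ± 1.20 and 3.24 ± 0.465 (exact p = 0.179), adipocyte scores 2.72 ± 0.549 and 1.97 ± 0.506 (exact p = 0.125). PCSK1N, a neuroendocrine secretory protein chosen after its values were seen, was at 11.0 ± 5.30 CPM in obese and 2.83 ± 1.68 in lean pancreas.

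The single libraries entered no comparison. Of the 1195 genes between lean pancreas and jejunum, the obese jejunum library lay nearer jejunum for 773 (64.7%). Of the 718 genes between pancreas and spleen/PLN, the lean PLN library lay nearer spleen/PLN for 557 (77.6%) and the obese PLN library for 617 (85.9%). For the 148 genes between jejunum and spleen/PLN these were 118 (79.7%) and 127 (85.8%). The genes were picked because these same tissue means differ, and no baseline share was set beside the percentages. The lean PLN library also shares its donor with libraries in the lean pancreas, jejunum and spleen/PLN means. The percentages therefore do not measure how alike a single library and a tissue are. The library with conflicting tissue labels was at 30.9 on the first and −29.4 on the second component.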
